A study of Mus musculus with 22 samples.

How the data were processed

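RNA was sequenced from E14 cells, a line of mouse embryonic stem cells grown with leukemia inhibitory factor on gelatin, 3 days after transfection with small interfering RNAs (siRNAs). Per the labels' protocols, total RNA was taken with Trizol, treated with DNase, purified on columns and made into libraries with a stranded mRNA kit. There were 22 libraries of 6 kinds: siNT with siNT (called siNT below), and siRpl14, siRpl11 or siDux, each given together with siNT, and the pairs siRpl14 with siRpl11 and siRpl14 with siDux. What NT stands for is not spelled out in the labels, and siNT is treated here as the control.

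The values used are FPKM (fragments counted per length of transcript and size of library) for 24819 genes, as deposited by the authors in 2 tables with 1 column per library. Reads were aligned with STAR and values made with Cuffnorm on the genome build mm9, per the submitters' processing notes. The versions, gene annotation, strand setting and normalization method are not given in the sources used here. The tables may have been normalized separately, so every test was made within a table. Levels from different tables are set side by side only as descriptions. Libraries were placed in 3 sets by the table and the style of their titles. Set 1 (8 libraries, 2 each of siNT, siRpl14, siRpl11 and siRpl14+siRpl11) and set 2 (4 libraries, 1 each of siNT, siDux, siRpl14 and siRpl14+siDux) share a table. Set 3 (10 libraries) is the other table, with 2 each of siNT, siDux, siRpl14 and siRpl14+siDux and 1 each of siRpl11 and siRpl14+siRpl11. That sets 1 and 2 are separate experiments is read from the title style alone. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

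Read counts were not used here, so absolute depth is unknown. Genes listed at 0 made up 30.1 to 32.1% of the genes per library in sets 1 and 2 and 50.5 to 56.2% in set 3. The 10th percentile of the values above 0 was 0.0538 to 0.0821 FPKM in sets 1 and 2 and 1.08 to 1.6 FPKM in set 3, so low values are resolved far less finely in set 3. From the commonest ratio among low genes, the other libraries of set 3 were estimated at 0.616 to 1.16 times the depth of replicate 1 of siDux. Across genes with a mean of 5 FPKM or more, replicates correlated at r = 0.976 to 0.98 in set 1 and at r = 0.813 to 0.853 in set 3, where genes are not independent replicates. In set 3 some genes of general cell function are listed at or near 0 (Tmem256 and Dpm3 at 0, Atp5g1 at a mean of 2.2 FPKM against 265 FPKM in sets 1 and 2), so a 0 there is reported as listed at 0, with no fold.

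Each of sets 1 and 3 was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with trended and robust empirical Bayes moderation, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 libraries of the fit were kept, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The single siRpl11 and siRpl14+siRpl11 libraries of set 3 were left out of its fit, and set 2 was not tested. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Errors are SD for FPKM and SE for log2 fold changes, with n = 2 per group unless stated. There were 5 contrasts per set: 2 single knockdowns and the combined knockdown against siNT, the combined knockdown against siRpl14, and the interaction (the change in the combined knockdown beyond the sum of the single ones). The difference between adding siRpl11 and adding siDux to siRpl14 lies between tables and was not tested.

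There were 17 gene lists with 601 entries, of which 16 are not in the tables, written before the data were examined, as were the tests, the other settings listed below and the naming rule. They hold genes of the 2C-like state and targets of Dux, p53 targets, pluripotency genes, cytosolic ribosomal protein genes other than Rpl14 and Rpl11, ribosome biogenesis, ATF4 and integrated stress response genes, markers of primitive endoderm, trophectoderm, early lineages and fibroblast feeders, interferon response, S phase, G2/M phase, replication-dependent histones, germline genes, cholesterol synthesis and glycolysis. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation beside it. A different question, whether a list changed at all rather than more than other genes, was asked with fry, so its p is not a p for the camera difference. The written plan named camera and the preset correlation but no other argument. The function's default form is the one reported; a form with a mean-variance trend and a form on ranks of moderated t were run too, and the ranked form was the first one looked at. Single libraries were described by a list's median difference and its place among 10000 random lists matched on mean expression in 20 bins.

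Named genes are the siRNA targets; the 5 raised and 5 lowered genes with the largest change in each of 4 main contrasts (siRpl14 against siNT in sets 1 and 3, and each combined knockdown against siRpl14) and 2 of each in the others, among genes past the threshold with a group mean of at least 1 FPKM and, except for an interaction, no overlap between groups; up to 3 members with the smallest adjusted p of each list past its test in the main contrasts; and Cdkn1a, Mdm2, Trp53, Zscan4c, Zscan4d, Zfp352, Pou5f1, Sox2 and Nanog. Some genes that the rule picks are left out of the text. Members of small counts outside this rule are named after their values were seen. Genes are identified by symbol, as deposited, and no coordinates are given because an mm9 annotation was not used here. Gene structures by symbol came from GENCODE M21, matched for 24300 genes, and served only to find genes whose exons overlap a gene on the opposite strand. Values of members of near-identical families (Zscan4, Usp17l, Trim43, the related Gm genes of the 2C-like list, and Rpl14 with Rpl14-ps1) are uncertain, since shared reads could be divided among them.

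The fit was tested on simulated data for the siRpl14 contrast, with 200 genes changed by known folds. These genes were drawn from those with a mean of at least 5 FPKM, so recovery of lower genes was not measured. The simulated noise was independent between libraries. In set 1 (12129 genes) the fit recovered 70.1% of 2-fold, 95.5% of 4-fold and 100% of 8-fold changes, and 13 of 190 calls were unchanged genes. In set 3 (13189 genes) it recovered 1.49%, 32.8% and 56.1%, and 4 of 64 calls were unchanged genes. Other settings were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, the replicate number as a block, all libraries of the table, limma without trend and robust moderation, and leaving out each library. The removal of genes overlapping an opposite-strand gene and the further camera forms were added after seeing the data. With 2 libraries per group, no regrouping of samples was counted.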

Results

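The data describe how mouse embryonic stem cells changed when the ribosomal protein genes Rpl14 and Rpl11 and the transcription factor gene Dux were depleted alone or in pairs. Rpl14 and Rpl11 encode proteins of the large ribosomal subunit. Rpl11 protein is also known to bind Mdm2, the ubiquitin ligase that limits p53. Dux activates genes of the 2-cell embryo, a program also seen in the rare 2C-like cells of such cultures. The series title names siRpl14 with siDux or siRpl11, so the main questions are what siRpl14 changed and how adding siRpl11 or siDux altered that change.

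The siRNA targets were measured first. In set 1, Rpl14 stood at 893 and 402 FPKM in the siRpl14 libraries against 1550 and 1417 FPKM in siNT, which is 60.2% and 27.1% of the siNT mean, and at 15.6% and 35.3% in siRpl14+siRpl11. The fall of Rpl14 with siRpl14 in set 1 was -1.31 ± 0.42 (SE; limma, adjusted p = 0.0479), and this call was lost when any of 5 libraries (either siNT or siRpl11 library, or siRpl14 replicate 2) was left out. Rpl11 was at 34.9% and 15.2% of siNT with siRpl11 and at 13.2% and 33.4% with both siRNAs, a change of -2.10 ± 0.46 (limma, adjusted p = 0.00992) with siRpl11 alone. In set 2, Rpl14 was at 34.6% of siNT with siRpl14 and 35.1% with siRpl14+siDux. In set 3 it was at 26.8% and 24.6% with siRpl14 (-1.95 ± 0.17, limma, adjusted p = 0.00672), at 28.8% and 22.7% with siRpl14+siDux, and at 17.7% in the single siRpl14+siRpl11 library. Rpl11 was at 19.2% and 23.7% in the single siRpl11 and siRpl14+siRpl11 libraries of set 3. Dux was at 0.306 FPKM in siNT, 0.0546 with siDux, 1.495 with siRpl14 and 0.168 with both in set 2. In set 3 Dux was listed at 0 in every library except siRpl14 replicate 2 (3.03 FPKM), so the siDux labels of that set could not be checked on the target itself. Rpl14-ps1, a pseudogene that shares sequence with Rpl14, was at 51.8% and 28.6% of siNT with siRpl14 in set 1.

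**Figure D1:**
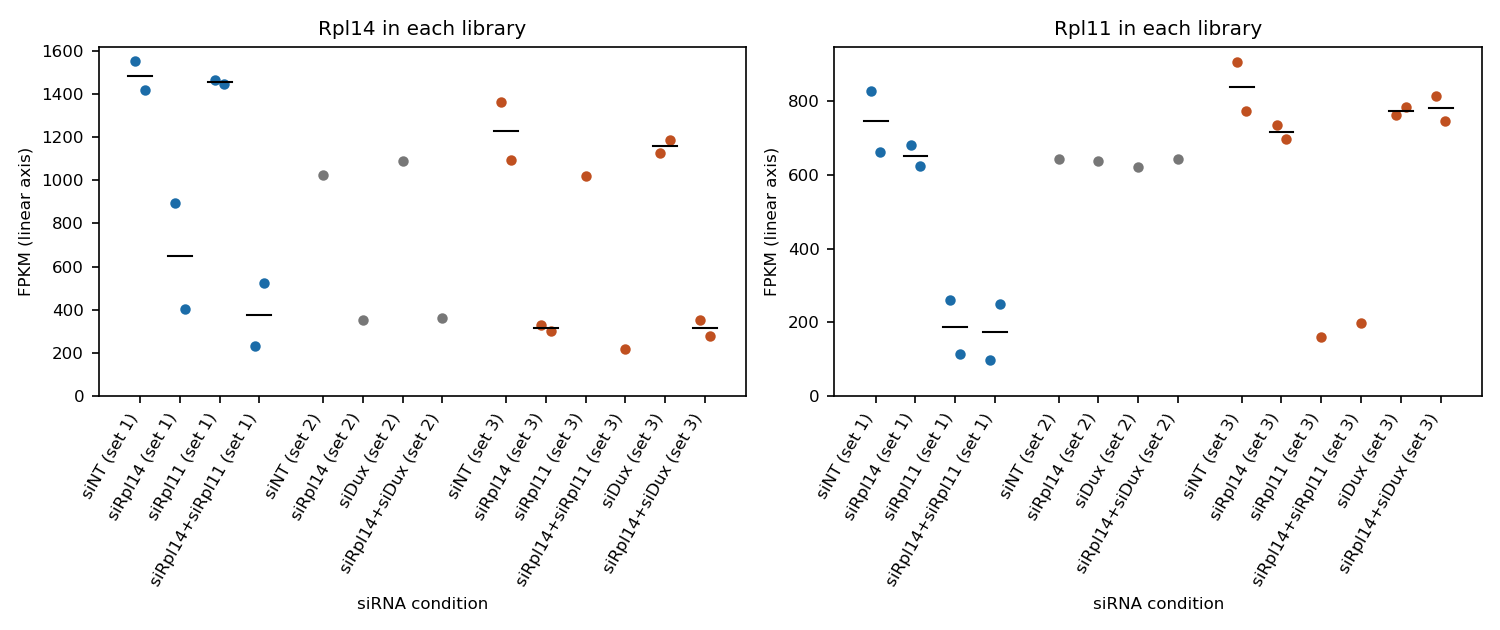
FPKM of Rpl14 and Rpl11 in each library of the 3 sets on a linear axis; each point is a library and each black bar the mean of 2 libraries. The siRpl14 libraries of set 1 lie at 893 and 402 FPKM of Rpl14. Sets 1 and 2 and set 3 come from different tables, which may have been normalized separately.

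Depletion of Rpl14 in set 1 raised the 2C-like genes and most p53 targets together. All 30 tested members of the 55 in the 2C-like list rose, with a median log2 fold change of 1.35, and 30 also rose adjusted over the list alone (limma camera, adjusted p = 5.59e-20; adjusted p = 0.316 with an estimated correlation). Zscan4d, a marker of the 2C-like state, went from 12.02 ± 0.971 to 36.0 ± 0.354 FPKM (SD, n = 2), a log2 fold change of 1.51 ± 0.12 (limma, adjusted p = 0.000665). Usp17lb, a deubiquitinase gene of a multicopy family, went from 2.02 ± 0.0202 to 14.7 ± 0.943 FPKM, Usp17la from 2.07 ± 0.348 to 11.01 ± 0.59 and Gm2022 from 3.04 ± 0.136 to 13.9 ± 0.871. Zscan4c rose by 1.28 ± 0.12 (limma, adjusted p = 0.00118) and Zfp352 by 1.28 ± 0.15 (limma, adjusted p = 0.00216). Dux itself rose from 0.285 ± 0.117 to 1.28 ± 0.24 FPKM (limma, adjusted p = 0.00789), and this call was lost without siNT replicate 2. It was not tested without either siRpl14 library, since Dux then missed the expression filter. The other 25 members missed that filter from the start or had no matching symbol in the table, and some members met it only through the siRpl14 libraries, as Zfp352 did (2.34 and 2.07 FPKM, under 1 in the other 6 of set 1), which favours genes that rose. The median was 1.277 with no filter and 1.592 with the stricter one, and the list passed in both.

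Of 39 p53 targets, 30 rose and 2 (Sesn1 and Xpc) fell, 31 and 3 adjusted over the list alone, with a median of 0.89 (limma camera, adjusted p = 5.46e-09; adjusted p = 0.552 with an estimated correlation). Mdm2 rose from 56.8 ± 13 to 327 ± 118 FPKM, by 2.48 ± 0.28 (limma, adjusted p = 0.00182). Perp, an effector of p53-dependent death, rose from 12.3 ± 3.07 to 149 ± 87 FPKM, the death receptor gene Fas from 0.328 ± 0.207 to 9.95 ± 3.66 and D630023F18Rik from 5.09 ± 1.09 to 39.4 ± 13.7. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 89.1 ± 38.9 against 70.4 ± 9.7 FPKM and did not pass (limma, adjusted p = 0.474), although it passed without siRpl14 replicate 1. The p53 gene Trp53 rose by 1.00 ± 0.26 (limma, adjusted p = 0.0254), a call lost without either siNT library or siRpl14 replicate 2.

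Genes of metabolism and the cell cycle were lower in the same comparison. Of 21 cholesterol synthesis genes 15 fell (17 adjusted over the list alone; median -0.68), among them Insig1 (-1.68 ± 0.19) and Msmo1 (-1.39 ± 0.19). Of 20 glycolysis genes 10 fell (13 adjusted over the list alone; median -0.75), among them Gapdh, Gpi1 and Hk1. Their camera tests gave adjusted p = 3.77e-08 and 1.42e-05, and adjusted p = 0.552 with an estimated correlation for each. Of 33 ATF4 and integrated stress response genes 15 fell and 3 (Ddit4, Cebpb and Ppp1r15a) rose, 17 and 3 adjusted over the list alone, with a median of -0.59 (limma camera, adjusted p = 0.000286; adjusted p = 0.552 with an estimated correlation). Nupr1, a stress-response regulator, fell from 69.1 ± 4.38 to 11.1 ± 6.23 FPKM and Nars, asparaginyl-tRNA synthetase, by 0.86, while Ppp1r15a, which promotes the removal of phosphate from eIF2alpha, rose by 1.13 ± 0.15. Of 28 S phase genes 10 fell, with E2f1 at -0.98 ± 0.17, Cdc45 at -0.62 ± 0.13 and Cdt1 at -0.47 ± 0.11, and 1 (Hells) rose (13 and 1 adjusted over the list alone; median -0.32; limma camera, adjusted p = 0.00124; adjusted p = 0.558 with an estimated correlation). Of 30 G2/M genes 12 fell, including Cenpa, Cdc25b and Kif23, and 14 did so adjusted over the list alone (median -0.30; limma camera, adjusted p = 1.42e-05; adjusted p = 0.552 with an estimated correlation). Of 40 histone genes 6 fell, including Hist1h2ah, Hist3h2a and Hist2h4, and 3 did so adjusted over the list alone (median -0.17; limma camera, adjusted p = 0.0313; adjusted p = 0.552 with an estimated correlation).

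Of 49 ribosome biogenesis genes 19 rose and 1 (Nop10) fell (21 and 1 adjusted over the list alone; median 0.28; limma camera, adjusted p = 0.000261; adjusted p = 0.552 with an estimated correlation), among them Utp20 (0.95 ± 0.15), Polr1e (0.89 ± 0.12) and Rrp12 (0.83 ± 0.11). The 79 other ribosomal protein genes had a median of -0.18, which became 0.01 under quantile normalization (limma camera, adjusted p = 0.00214; adjusted p = 0.774 with an estimated correlation). Rpl3 (-0.96 ± 0.28) and Rpl22 (-0.50 ± 0.16) fell, and none passed adjusted over the list alone. Rpl22l1, a paralog of Rpl22, was at 80.0 ± 18.4 against 46.8 ± 1.6 FPKM and did not pass (limma, adjusted p = 0.0637). Of 9 early lineage markers 5 (Pou3f1, Dnmt3b, Wnt3, Nes and Snai1) rose and 6 did so adjusted over the list alone (median 1.04; limma camera, adjusted p = 0.0377; adjusted p = 0.552 with an estimated correlation). Wnt3 rose by 2.28 ± 0.44, Nes by 1.26 ± 0.18 and Dnmt3b by 0.62 ± 0.13. The pluripotency list did not pass (median -0.10, camera adjusted p = 0.836), with 10 of 35 members higher and 7 lower. Sox2 rose by 0.34 ± 0.11 (limma, adjusted p = 0.0439), a call lost when any 1 of the 8 libraries was left out. Pou5f1 was at 848 ± 47 against 948 ± 3.87 FPKM and Nanog at 254 ± 23.3 against 364 ± 21, and neither passed.

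In all, 3822 of 12129 genes passed in this comparison, 2191 higher and 1631 lower, with 512 and 312 at least 2-fold. Under quantile normalization 2018 were higher and 2057 lower. The genes with the largest rises were Fgfbp1 (1.58 ± 0.454 to 80.7 ± 60.8 FPKM), Ms4a10, Cpz, Perp and Cd80, and those with the largest falls were Nupr1, Lrrc31, Tgm2, Vegfa and Inhbb. The count was 752 without siNT replicate 1, 1419 without siNT replicate 2 and 791 without siRpl14 replicate 2. The set 2 library pair, which has no replicate check, showed the same direction for 3738 (97.8%) of these genes. Lists did not all agree: in set 2 ribosome biogenesis had a median of 0.02 (27 of 49 above 0) and the other ribosomal protein genes -0.07, both within the central 95% of random lists, and pluripotency one of -0.48, below all 10000. In it Mdm2 was at 472 against 51.4 FPKM and Zscan4d at 58.1 against 26.1.

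**Figure D2:**
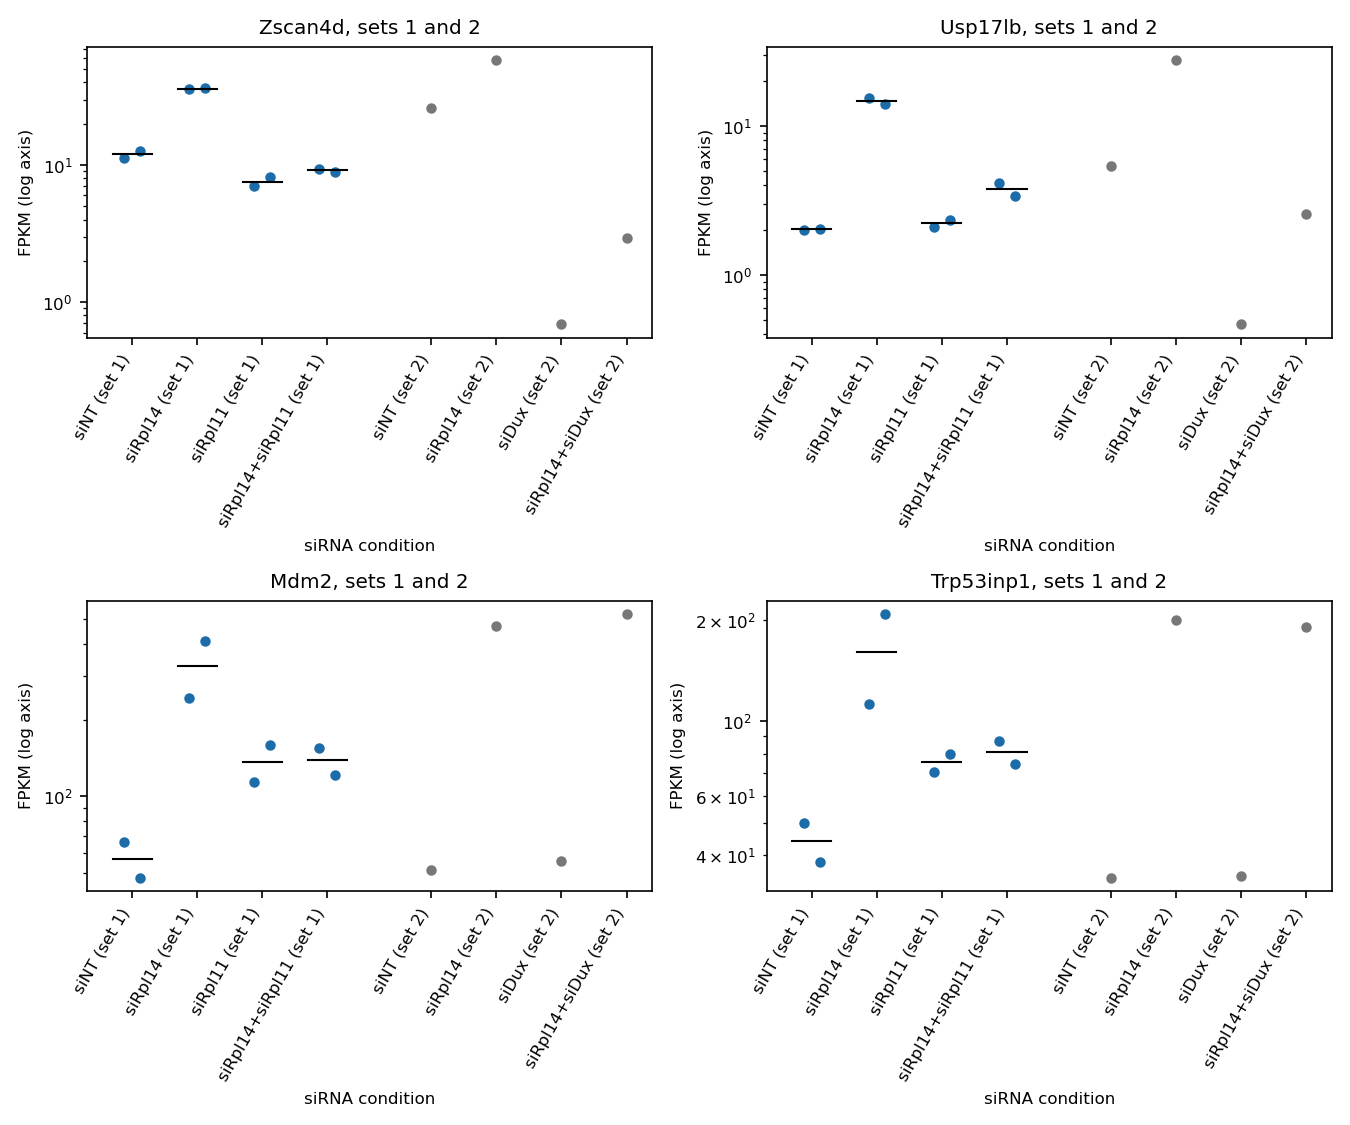
FPKM of Zscan4d, Usp17lb, Mdm2 and Trp53inp1 in each library of sets 1 and 2 on a log axis. Zscan4d lies at 35.7 and 36.2 FPKM in the siRpl14 libraries of set 1 and at 9.42 and 8.93 in siRpl14+siRpl11.

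Depletion of Rpl11 alone did not raise the 2C-like list and changed many other genes. Its median was -0.16, which became 0.03 under quantile normalization, with 0 members higher and 6 of 30 lower (4 adjusted over the list alone), among them Zscan4a, Zscan4c, Zscan4d and Zscan4f (limma camera, adjusted p = 0.236). Of 39 p53 targets 15 rose and 4 (Sesn1, Gdf15, Xpc and Dcxr) fell (15 and 4 adjusted over the list alone; median 0.28; limma camera, adjusted p = 0.0171; adjusted p = 0.842 with an estimated correlation). Of 49 ribosome biogenesis genes 35 rose (37 higher and 2 lower adjusted over the list alone; median 0.52; limma camera, adjusted p = 4.47e-11; adjusted p = 0.781 with an estimated correlation). Otx2, a transcription factor of the primed epiblast, rose from 10.9 ± 2.42 to 98.4 ± 9.29 FPKM, by 3.08 ± 0.17 (limma, adjusted p = 0.00112), and Tspan8 by 3.09 ± 0.26. Lrrc31 fell by 2.71 and Tgm2 fell by 2.65. The ATF4 (median -0.68), cholesterol synthesis (-0.61) and glycolysis (-0.67) lists were lower, with 21 of 33, 15 of 21 and 11 of 20 members that fell and 22, 16 and 11 adjusted over the list alone. Their camera tests gave adjusted p = 0.00855, 0.000302 and 0.00855, and adjusted p = 0.794, 0.781 and 0.842 with an estimated correlation. The ribosomal protein list was higher (median 0.12; camera adjusted p = 0.0069; adjusted p = 0.842 with an estimated correlation), as were the early lineage markers (median 0.56; camera adjusted p = 0.0318; adjusted p = 0.781 with an estimated correlation). In all 5377 genes passed, 1938 higher and 3439 lower. The share higher was 36%, against 50% after median-ratio rescaling and 51.5% after quantile normalization, and the median of all genes moved from -0.11 to -0.01 and 0.01, so the balance of directions depends on the scaling. The count was 2084 without siNT replicate 1, 2972 without siNT replicate 2 and 1778 without siRpl11 replicate 2.

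The single knockdowns share the siNT libraries. Among genes tested in both, 1139 were higher and 1427 lower with each siRNA, where independent lists would share 350 and 462, and 69 went opposite ways. The fold changes correlated across genes at r = 0.751, against 0.503 for simulated unchanged groups set against the same controls, with a covariance of 0.253 against 0.027, a difference of 0.226. With 2 siNT libraries the controls were not split, and part of the excess may come from them. Against the siRpl14 change of the set 2 libraries, which have their own siNT, the siRpl11 change of set 1 correlated at r = 0.565.

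Adding siRpl11 to siRpl14 brought the 2C-like genes back down. All 30 tested members were lower in siRpl14+siRpl11 than in siRpl14, 30 also adjusted over the list alone, with a median of -1.45 (limma camera, adjusted p = 2.68e-31; adjusted p = 0.145 with an estimated correlation). Zscan4d fell from 36.0 ± 0.354 to 9.18 ± 0.346 FPKM (-1.86 ± 0.12, limma, adjusted p = 0.000961), Zscan4c from 25.1 ± 0.818 to 8.07 ± 0.481, Gm2022 from 13.9 ± 0.871 to 3.46 ± 0.206, Usp17lb from 14.7 ± 0.943 to 3.76 ± 0.541 and Zfp352 from 2.21 ± 0.187 to 0.401 ± 0.0906. Against siNT the combined knockdown had a median of 0.08 (camera adjusted p = 0.368), with Usp17lb and Tmem92 higher and Zscan4a, Zscan4d and Zscan4f lower (1 higher and 0 lower adjusted over the list alone). Dux was at 0.606 ± 0.115 against 1.28 ± 0.24 FPKM in siRpl14 and did not pass (limma, adjusted p = 0.0877). These are the same 30 members, and the median was -1.222 with no filter and -1.685 with the stricter one, where the list passed too.

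The p53 targets were lower too. Of 39 members 14 fell and 0 rose (22 and 0 adjusted over the list alone), with all 39 fitted below 0 and a median of -0.61 (limma camera, adjusted p = 1.1e-07; adjusted p = 0.581 with an estimated correlation; against no change, fry adjusted p = 0.165). Fas fell by 1.56, Dcxr by 1.53, the apoptosis gene Apaf1 by 0.98 and Mdm2 by 1.20 (limma, adjusted p = 0.0419), and all 4 calls were lost without siRpl14 replicate 2 or siRpl14+siRpl11 replicate 2. Those of Dcxr, Apaf1 and Mdm2 were also lost without siRpl14+siRpl11 replicate 1, and that of Mdm2 without either siNT library. The list's median was -0.35 without siRpl14 replicate 2 and -0.93 without siRpl14 replicate 1. Cdkn1a (59.7 ± 10.6 against 89.1 ± 38.9 FPKM) and Trp53 (509 ± 114 against 327 ± 98.4) did not pass. Against siNT the p53 list remained higher in the combined knockdown, with 19 members that rose and 3 (Sesn1, Gdf15 and Xpc) that fell (21 and 3 adjusted over the list alone; median 0.44; limma camera, adjusted p = 0.00157; adjusted p = 0.867 with an estimated correlation).

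Of 16 trophectoderm markers, genes of the outer layer of the blastocyst, 4 (Krt7, Krt8, Krt18 and Tfap2c) fell with siRpl11 added (8 lower and 1 higher adjusted over the list alone; median -0.38; limma camera, adjusted p = 0.0295; adjusted p = 0.581 with an estimated correlation). Krt7 fell from 4.05 ± 1.14 to 0.538 ± 0.216 FPKM, Krt8 from 9.88 ± 4.37 to 2.54 ± 0.46 and Tfap2c from 35.2 ± 7.48 to 16.7 ± 0.555. Ribosomal protein genes were higher as a list (median 0.19, 0 under quantile normalization; 1 of 79 passed, Rps2, and 0 adjusted over the list alone), as were ribosome biogenesis (median 0.14), S phase (0.11), G2/M (0.11), histone (0.18, but -0.32 over the 7 members left by the stricter filter) and cholesterol synthesis genes (0.06). These sizes depend on scaling. Median-ratio rescaling gave 0.30 for ribosomal protein genes and 0.24, 0.21, 0.22, 0.26 and 0.17 for the last 5 lists. Quantile normalization gave 0.13, 0.16, 0.21, 0.40 and 0.18 for the last 5. The camera tests of the 6 lists gave adjusted p = 1.42e-13, 1.53e-06, 7.15e-05, 1.28e-05, 0.000362 and 0.0295; with an estimated correlation adjusted p = 0.641 for cholesterol synthesis and adjusted p = 0.581 for each of the others. Few members passed: Gnl3 rose by 0.37 and Polr1e fell by 0.64 in ribosome biogenesis, Cdt1 (0.46 ± 0.11) and Mcm5 (0.41 ± 0.10) rose in S phase, and Hist1h2bl rose and the linker histone gene Hist1h1c fell by 2.05. No G2/M or cholesterol synthesis gene passed (limma), also adjusted over the list alone. Rpsa, Rplp2, Nop56, Hells, Kif11, Bub1, Cenpf, Hist1h4f, Mvk, Srebf2 and Lss had adjusted p between 0.0522 and 0.376. Nanog fell from 254 ± 23.3 to 151 ± 43.2 FPKM (limma, adjusted p = 0.0489), a call lost without any of 7 libraries, while Pou5f1 (adjusted p = 0.24) and Sox2 (adjusted p = 0.91) did not pass.

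In all 878 of 12129 genes passed, 76 higher and 802 lower. The share higher was 8.66%, against 20.4% after median-ratio rescaling and 22.9% after quantile normalization, as the median of all genes moved from -0.09 to 0 and 0.04. Fgf15, Car14, Vrtn and Glod5 were among the genes that rose most, and Sct, Cpz, Rgs14, LOC105246046 and Sfn, a p53-responsive 14-3-3 gene, fell most. Sct fell by 2.76 (SE 0.24) and Sfn from 29.3 ± 10.6 to 6.01 ± 2.41 FPKM. The count was 79 without siRpl14 replicate 2 and 138 without siRpl14+siRpl11 replicate 1, both under the 394 to 670 of the other 6 omissions. Against siNT the combined knockdown changed 5043 genes, 2008 higher and 3035 lower (39.8% higher, 48.8% and 51.9% under the other scalings), with Pim2 and Otx2 raised and Lrrc31 and Tgm2 lowered most. That count was 1307 without siRpl14+siRpl11 replicate 1, 1535 without siNT replicate 1 and 2379 without siNT replicate 2. There the ribosome biogenesis (median 0.43) and early lineage (0.58) lists were higher and the ATF4 (-0.71), cholesterol synthesis (-0.61) and glycolysis (-0.69) lists lower. Their camera tests gave adjusted p = 2.35e-08, 0.0224, 0.00196, 0.000186 and 0.00482, and adjusted p = 0.867 with an estimated correlation for each.

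The interaction of siRpl14 and siRpl11 passed for 544 genes, 222 higher and 322 lower, and for 27 (2 higher and 25 lower) with the replicate block, 145 with the stricter filter, 313 with no filter and 1811 with all libraries of the table. Mlana (-3.55 ± 0.43, limma, adjusted p = 0.0183) and Cd80 (-3.22 ± 0.56) rose with either siRNA alone but less with both than the sum, and Nupr1 (2.48 ± 0.52) and Tgm2 (2.12 ± 0.43) were lowered by either without a further equal fall. The count was 2 without siNT replicate 2, 3 without siNT replicate 1, 6 without siRpl14+siRpl11 replicate 2, 20 and 27 without siRpl11 replicates 1 and 2, 36 without siRpl14 replicate 2, 273 without siRpl14+siRpl11 replicate 1 and 1199 without siRpl14 replicate 1.

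**Figure D3:**
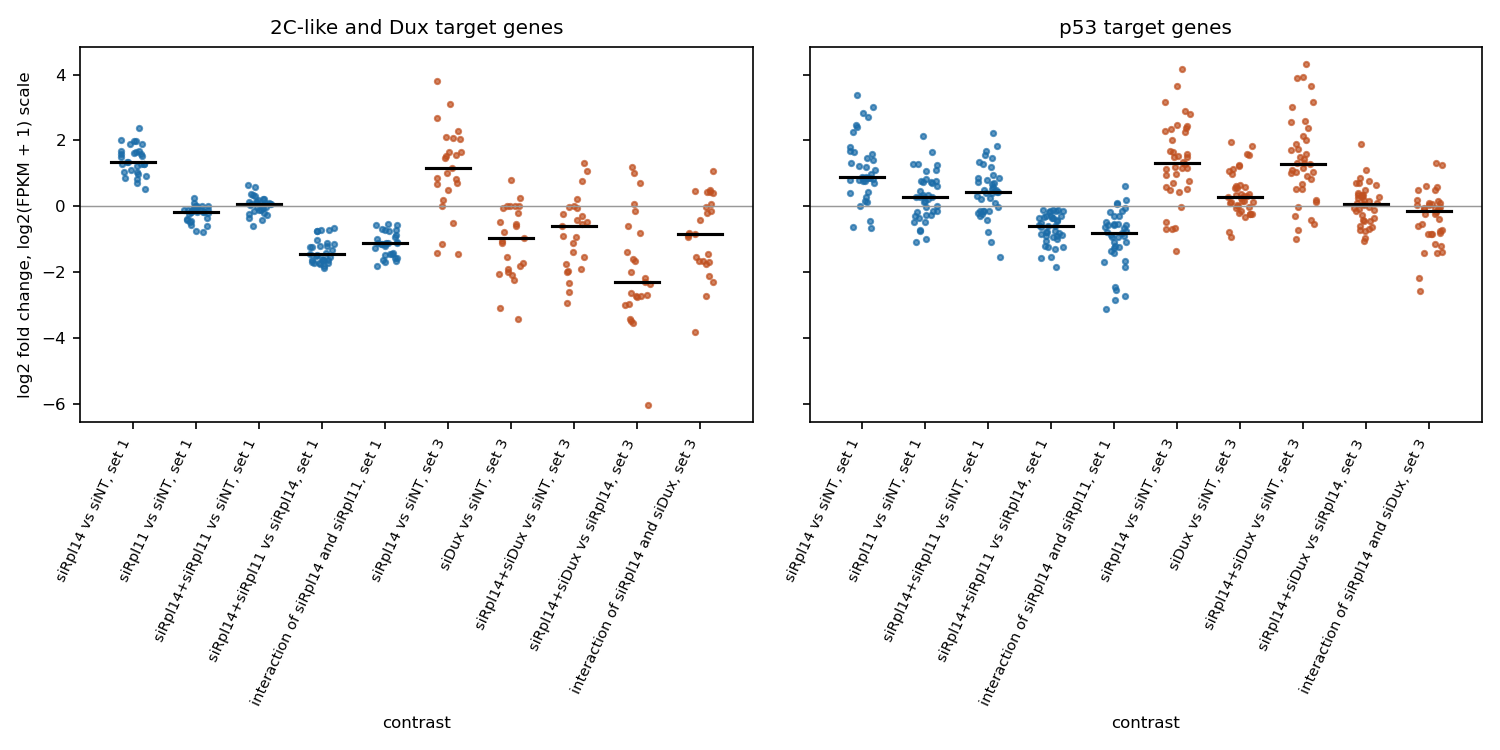
Fitted log2 fold change of each tested member of the 2C-like and p53 lists in the 10 contrasts, on the log2(FPKM + 1) scale; points are genes, black bars medians, blue set 1 and orange set 3. The 2C-like median is 1.35 with siRpl14 in set 1 and -1.45 when siRpl11 is added.

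In set 3 siRpl14 raised the p53 and 2C-like lists again. Of 38 p53 targets 5 (Mdm2, Ccng1, Trp53inp1, Plk2 and Perp) rose and 0 fell, 21 and 1 adjusted over the list alone, with a median of 1.32 (limma camera, adjusted p = 4.61e-14; adjusted p = 0.0426 with an estimated correlation). Perp went from 4.04 ± 1.33 to 88.2 ± 9.67 FPKM, Plk2 from 2.61 ± 0.41 to 44.2 ± 1.38, Trp53inp1 from 38.5 ± 3.93 to 157 ± 17.5 and Mdm2 from 17.6 ± 3.76 to 135 ± 11.1 (2.89 ± 0.37, limma, adjusted p = 0.0229). Of 25 2C-like genes 0 passed over all genes and 5 rose and 2 fell adjusted over the list alone, with 21 fitted above 0 and a median of 1.18 (limma camera, adjusted p = 2.91e-06; adjusted p = 0.0426 with an estimated correlation). Over the 20 members above 0 in some library of each group the median was 1.10. With the stricter filter 7 members were left and the call was lost (adjusted p = 0.325). Trim75 was at 163 ± 23 against 38.1 ± 6.5 FPKM, Zscan4c at 10.6 ± 1.01 against 2.76 ± 0.864 and Trim43c at 2.66 ± 0.192 against 8.85 ± 0.911, while Gm12794 was listed at 0 in both siNT libraries and at 14.01 and 12.3 in siRpl14. Exons of Trim43c overlap a gene on the opposite strand, so its set 3 values are uncertain. Zscan4d was at 1.77 and 6.26 FPKM against 2.09 and 4.04, and Zfp352 was listed at 0 in both siNT libraries and siRpl14 replicate 1 and at 1.82 in replicate 2.

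Of 20 glycolysis genes, Ldha fell from 785 ± 95.2 to 339 ± 24.9 FPKM and 15 fell adjusted over the list alone (median -0.99; limma camera, adjusted p = 1.08e-09; adjusted p = 0.0975 with an estimated correlation), with Aldoa at 318 ± 58.5 against 609 ± 44.8 and Pgk1 at 199 ± 31.4 against 449 ± 98.2. Of 32 ATF4 genes Phgdh, an enzyme of serine synthesis, fell from 45.5 ± 0.314 to 5.71 ± 2.93 FPKM, and 6 fell and 1 rose adjusted over the list alone (median -0.70; limma camera, adjusted p = 0.000494; adjusted p = 0.131 with an estimated correlation); Psat1 was at 14.9 ± 2.21 against 59.3 ± 21.1 and Nars at 57.6 ± 11.2 against 129 ± 2.47. The early lineage list was higher (median 1.15, 0 of 11 passed; camera adjusted p = 0.00016; adjusted p = 0.0703 with an estimated correlation); Pax6 was at 27.6 ± 4.82 against 10.7 ± 1.1 FPKM, and Pou3f1 was listed at 0 in siNT and at 5.00 and 5.81 in siRpl14. The S phase (median -0.46), G2/M (-0.50), cholesterol synthesis (-0.50) and ribosomal protein (-0.14) lists were lower, with 0 members past the test over all genes (limma). Their camera tests gave adjusted p = 0.000385, 0.0127, 0.0454 and 0.0411, and adjusted p = 0.195, 0.222, 0.222 and 0.563 with an estimated correlation. Adjusted over the list alone 4 ribosomal protein genes and 1 G2/M gene fell and 1 G2/M gene rose. Examples that did not pass are E2f1 (4.93 ± 0.399 against 13.8 ± 4.79 FPKM), Mcm7, Uhrf1, Top2a (64.3 ± 8.53 against 128 ± 15.2), Ccnb2, Kif20a (540 ± 53.2 against 279 ± 31.7), Insig1 (11.5 ± 1.29 against 34.4 ± 6), Msmo1, Cyp51, Rpl3, Rpl10 and Rpl22l1 (331 ± 7.3 against 741 ± 202). Exons of Mcm7, Kif20a and Cyp51 overlap a gene on the opposite strand, so their set 3 values are uncertain. Cdkn1a, Trp53, Pou5f1, Sox2 and Nanog did not pass, with adjusted p of 0.293, 0.746, 0.676, 0.478 and 0.203 (limma).

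In all 87 of 13189 genes passed, 70 higher and 17 lower, and 1632 had an unadjusted p under 0.05. By the rule of largest change these were Ccdc85b (4.55 ± 1.3 to 304 ± 35 FPKM), Tsix (5.17 ± 2.84 to 151 ± 28.5) and Bfsp2 (2.48 and 0 to 51.7 and 71.5), with Gm9748 (66.3 and 49.7) and Gm10190 (41.5 and 69.8) listed at 0 in siNT. Ltc4s, Dad1, Gm15217, Zfyve21 and 1110008P14Rik were listed at 0 in both siRpl14 libraries and at 36.6 and 28.5, 11.98 and 61.3, 25.3 and 22.7, 23.7 and 6.77, and 6.73 and 11.9 FPKM in siNT. Exons of all 5 raised genes, Gm15217 and 1110008P14Rik overlap a gene on the opposite strand, and without such genes 39 passed. The count was between 8 and 45 when any 1 library was left out, with 8 and 10 without siRpl14 replicates 2 and 1 and 18 and 30 without siNT replicates 2 and 1.

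Fold changes of set 1 and set 3, each taken within its own table, were set side by side. Of the genes called in set 1 and measured in set 3, 75% (2574 of 3434) moved the same way with siRpl14, with r = 0.422 across 11144 genes. Genes raised by siRpl14 in set 1 had a median of 0.44 with siRpl14 in set 3 (limma camera, n = 2050 genes, p = 3.32e-15, and p = 0.00532 with an estimated correlation).

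Depletion of Dux alone lowered the 2C-like list in set 3. The median was -0.96, with 0 of 25 members past the test over all genes and 2 lower adjusted over the list alone (limma camera, adjusted p = 2.01e-07; adjusted p = 0.0535 with an estimated correlation), and 14 members were listed at 0 in both siDux libraries against 4 in both siNT libraries, which gives no fold. Over the 11 members above 0 in some library of each group the median was -1.04, with 9 below 0 and 2 above. The p53 list was slightly higher (median 0.29, 0 of 38 passed and 1 higher adjusted over the list alone; camera adjusted p = 0.00353; adjusted p = 0.335 with an estimated correlation) and glycolysis lower (median -0.30; camera adjusted p = 0.0231; adjusted p = 0.592 with an estimated correlation). A single gene passed, Gm9748 (18.8 and 18.6 FPKM, listed at 0 in siNT), and 660 had an unadjusted p under 0.05; no gene passed when any 1 library was left out (limma). In set 2, without replicates, Zscan4d was at 0.688 FPKM with siDux against 26.1, and the 2C-like median was -2.22, below all 10000 random lists.

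Adding siDux to siRpl14 lowered the 2C-like genes, and no change of the p53 targets was called. The 2C-like median was -2.29 against siRpl14 in set 3, with 21 of 25 members fitted below 0, 0 past the test over all genes, and 16 lower and 1 higher adjusted over the list alone (limma camera, adjusted p = 8.6e-14; adjusted p = 0.0162 with an estimated correlation). Trim75 was at 20.7 ± 8.92 against 163 ± 23 FPKM. Gm5039 and Zscan4c were listed at 0 in both siRpl14+siDux libraries, against 53.1 and 78.2, and 11.3 and 9.88, in siRpl14. Zscan4d and Zfp352 were listed at 0 in both siRpl14+siDux libraries too. Over the 12 members above 0 in some library of each group the median was -2.14. The p53 list had a median of 0.08 and 0 of 38 members passed (limma camera, adjusted p = 0.914), also adjusted over the list alone; Mdm2 was at 165 ± 10.9 against 135 ± 11.1 FPKM, a difference of 0.28 ± 0.37 that did not pass, and Cdkn1a at 65.9 ± 23.9 against 51.9 ± 5.69. The median was -0.09 without siRpl14 replicate 2. In set 2 Zscan4d was at 2.92 with both siRNAs against 58.1 with siRpl14, and Mdm2 at 526 against 472. The p53 median there was 0.08, with 25 of 39 members higher, slightly above the central 95% of random lists (-0.06 to 0.05). In set 3 few changes of 2-fold could be called, so the test there does not show that the p53 targets stayed the same.

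The pluripotency list was lower with siDux added (median -0.30, 0 of 35 passed, also adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.818 with an estimated correlation), with Fbxo15 at 34.0 ± 12.2 against 90.6 ± 24.3 FPKM, Tdgf1 at 233 ± 31.9 against 339 ± 35 and Lefty1 higher at 27.1 ± 9.18 against 8.48 ± 3.85. Pou5f1 (620 ± 39.2 against 639 ± 48.4), Sox2 and Nanog (219 ± 2.51 against 229 ± 24.4) did not pass. The cholesterol synthesis list was lower (median -0.41, 0 of 20 passed; camera adjusted p = 0.0403; adjusted p = 0.651 with an estimated correlation), with Nsdhl at 4.197 ± 2.26 against 10.2 ± 0.446 FPKM and Fdps at 0 and 3.52 against 8.53 and 7.35. In set 2 neither fall was seen: the pluripotency median was -0.03 (15 above and 20 below 0) and the cholesterol synthesis median 0.06 (15 of 20 above 0), each within the central 95% of random lists. Only 2 genes passed by limma, with 894 at an unadjusted p under 0.05: Mir6363, at 1772 and 1867 FPKM and listed at 0 in siRpl14, and Polr2k, listed at 0 and at 40.4 and 21.3 in siRpl14. A microRNA precursor is short and Mir6363 overlaps a gene on the opposite strand, and no gene passed without such genes or without either siRpl14+siDux library.

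Against siNT, siRpl14+siDux changed 135 genes in set 3, 94 higher and 41 lower, with Mir6363 and Ccdc85b raised most and Lamtor5 and Ltc4s listed at 0. The p53 list was higher, with 6 of 38 members that rose (20 adjusted over the list alone; median 1.29; limma camera, adjusted p = 1.65e-13; adjusted p = 0.0461 with an estimated correlation), and the 2C-like list lower (median -0.59, and -0.36 over the 10 members above 0 in some library of each group; camera adjusted p = 0.00231; adjusted p = 0.107 with an estimated correlation). Glycolysis (median -1.21; camera adjusted p = 4.21e-08) and cholesterol synthesis (median -1.05; camera adjusted p = 0.000985) were lower, and adjusted p = 0.107 with an estimated correlation for each. Early lineage markers were higher (median 1.06; camera adjusted p = 0.00146; adjusted p = 0.107 with an estimated correlation), as were trophectoderm markers (median 0.83; camera adjusted p = 0.0166; adjusted p = 0.119 with an estimated correlation). The S phase (median -0.57), G2/M (-0.45), ATF4 (-0.70), interferon response (-0.53), pluripotency (-0.33) and ribosomal protein (-0.25) lists were lower, with camera adjusted p = 0.000567, 0.00991, 0.00146, 0.0162, 0.0096 and 0.00911. With an estimated correlation adjusted p = 0.127, 0.187, 0.119, 0.119, 0.394 and 0.539. The count was 26 without siRpl14+siDux replicate 2, 28 and 48 without siNT replicates 2 and 1, and 79 to 90 without any of the other 5 libraries. Without siRpl14+siDux replicate 1 it was 80, with 33 higher and 47 lower, so the balance of directions rests on that library. The early lineage median was -0.05 over the 2 members left by the stricter filter. The interaction of siRpl14 and siDux passed for Mir6363 and Gm9748, with 699 genes at an unadjusted p under 0.05 (limma), and neither remained without genes that overlap an opposite-strand gene.

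**Figure D4:**
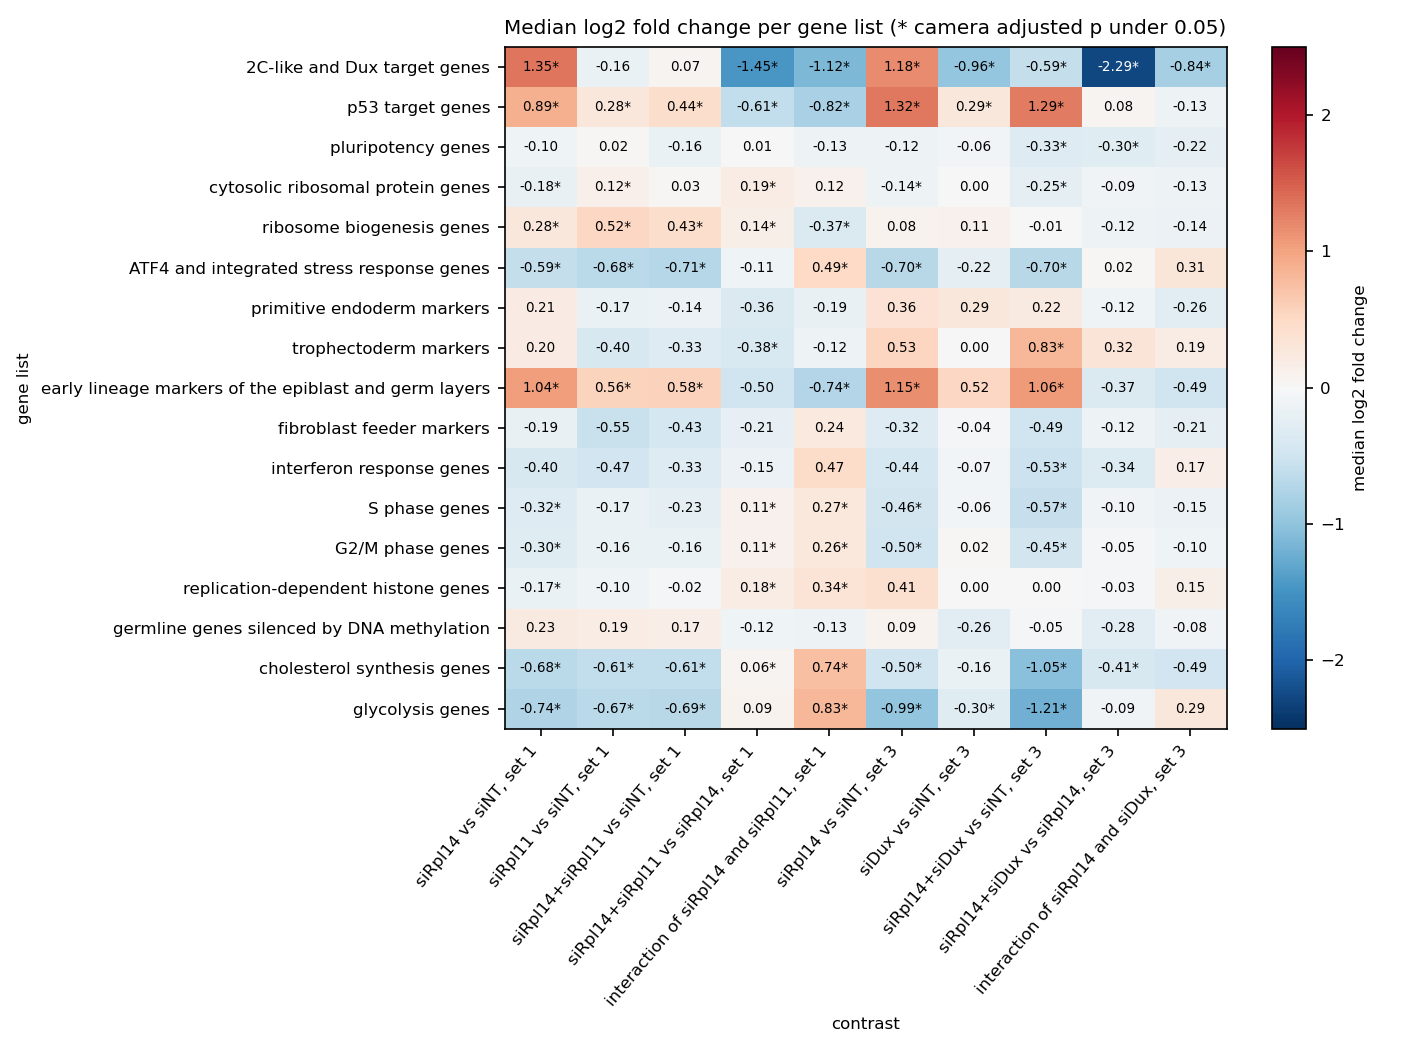
Median log2 fold change of each of the 17 gene lists in the 10 contrasts, on the log2(FPKM + 1) scale; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The p53 median is -0.61 when siRpl11 is added to siRpl14 in set 1 and 0.08 when siDux is added in set 3. These come from different tables, which may have been normalized separately.

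The genes that siRpl14 raised in one set were followed in the other set's combined knockdown. Of the 70 raised in set 3, 54 were measured in set 1, and 43 of them were lower in siRpl14+siRpl11 than in siRpl14, with a median of -0.40 (limma camera, n = 54 genes, p = 0.000405, and p = 0.241 with an estimated correlation). The call was lost without siRpl14 replicate 2 of set 1 (median -0.30), without either siNT library of set 3 (-0.28 for each), without siRpl14 replicates 1 and 2 of set 3 (-0.36 and -0.42), and with limma run without trend and robust moderation (-0.50). Of the 2191 raised in set 1, 2050 were measured in set 3 and had a median of -0.02 when siDux was added (limma camera, n = 2050 genes, p = 0.704). These comparisons lie in different tables, and the difference between them was not tested. The lists are also unlike. Of the 70 genes 69 rose at least 2-fold in set 3, against 512 of the 2191 in set 1. The longer list had a median of only 0.44 with siRpl14 in set 3, which leaves little room for a fall. The median of all genes was -0.09 with siRpl11 added in set 1 and 0 with siDux added in set 3.

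The single libraries of set 3 were described without a test. The siRpl14+siRpl11 library had a 2C-like median of -1.56 and a p53 median of -0.72 against the siRpl14 mean, each below all 10000 random lists. So was the histone median of -1.98 (13 measured, 10 lower), opposite to the histone median of set 1. Against siNT, however, the histone median of this library was 0 (2 above 0 and 6 below). The histone median was not recounted without members listed at 0. Of the 26 2C-like members 13 were listed at 0 in that library, which gives no fold, and over the other 13, all above 0 in some siRpl14 library, the median was -0.97 (11 below 0 and 2 above), not set against random lists. Mdm2 was at 47.5 FPKM and Trp53inp1 at 70.2 in that library, and at 59.1 and 79.2 in the single siRpl11 library.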

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

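The 3 tests of the fall of 2C-like genes with siRpl11 added were chosen after the result was seen. The results below were picked out because a test of the interaction passed, that is, the combined knockdown differed from the sum of the single ones.

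In set 1 the interaction was negative for the 2C-like list (median -1.118, limma camera, adjusted p = 1.48e-20; adjusted p = 0.301 with an estimated correlation), with 20 of 30 members lower and 28 lower adjusted over the list alone. It was negative too for the p53 targets (median -0.82, 9 of 39 lower, camera adjusted p = 1.2e-08), ribosome biogenesis (-0.369, 4 of 49 lower, adjusted p = 2.38e-06) and early lineage markers (-0.741, 0 of 9, adjusted p = 0.0364). It was positive for cholesterol synthesis (0.745, 7 of 21 higher, camera adjusted p = 2.62e-08), glycolysis (0.831, 0 of 20, adjusted p = 7.63e-05), ATF4 genes (0.489, 1 higher and 1 lower of 33, adjusted p = 0.00279), G2/M (0.258, 0 of 30, adjusted p = 0.000392), S phase (0.272, 0 of 28, adjusted p = 0.0125) and histone genes (0.335, 2 of 40 higher, adjusted p = 0.0134). With an estimated correlation these gave adjusted p = 0.592 for S phase and adjusted p = 0.522 for each of the other 8. For cholesterol synthesis, glycolysis and ATF4 genes, which were lower in each knockdown, a positive value means that the falls did not add up. Ribosome biogenesis was higher against siNT with siRpl14 (median 0.277), siRpl11 (0.518) and both (0.43), and with siRpl11 added to siRpl14 (0.137). Its negative value thus means that the rises did not add up. In set 3 the interaction of siRpl14 and siDux was negative for the 2C-like list (-0.838, 0 of 25 members, limma camera, adjusted p = 0.0118). It did not pass camera with an estimated correlation (adjusted p = 0.331) or in the ranked form (adjusted p = 0.0819). A larger effect of siDux after siRpl14 cannot be read from this sign, since genes at 0 fall no further. Of the 25 members 14 were listed at 0 in both siDux libraries and 12 in both siRpl14+siDux libraries. In set 2, without replicates, the list medians were -2.22 with siDux and -3.005 with siDux added to siRpl14. In FPKM, however, Zscan4c fell 19.3-fold and 17-fold there, and Zscan4d 37.9-fold and 19.9-fold.

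The fall of the 2C-like genes when siRpl11 was added to siRpl14 in set 1 was weighed against other explanations. A weaker depletion of Rpl14 was argued against: mean Rpl14 in the combined knockdown was 0.583 times that in siRpl14, and although single libraries overlapped (232 and 524 against 893 and 402 FPKM), Zscan4d was at 35.7 FPKM in the siRpl14 library with 893 FPKM of Rpl14 and at 8.93 in the combined library with 524. A general fall of genes at that expression level was argued against too, since the median of -1.451 lay below all 10000 matched random lists (central 95% from -0.297 to -0.049). Camera had already set the list against all other genes in the same values, so this adds only the matching on expression. Random lists also lack the near-identical families of this list. With an estimated correlation camera did not call the fall (adjusted p = 0.145). The p53 list had a median of -0.609 (random lists -0.136 to 0.043), the direction a smaller p53 response would need, so a p53-dependent part of the 2C-like rise stays open as a hypothesis. That support is limited: 14 of 39 members passed, the list did not pass with an estimated correlation (adjusted p = 0.581), a change against 0 was not called by fry (adjusted p = 0.165), and the median was -0.345 without siRpl14 replicate 2. Between siRpl14 replicates 1 and 2, the p53 targets Mdm2 (244 and 410 FPKM), Trp53inp1 (113 and 208) and Ccng1 (137 and 238) differed. Of the 2C-like genes, Zscan4d (35.7 and 36.2) hardly differed and Tmem92 (18.9 and 13.1) went the other way. Zscan4c (24.5 and 25.6) was slightly higher in replicate 2. These are picked genes in single libraries. Whether the 2C-like list as a whole followed the p53 targets between these replicates was not tested. With siRpl11 alone the p53 and 2C-like medians against siNT were 0.28 and -0.16, and with both siRNAs 0.44 and 0.08. The p53 targets were thus higher, by less than the 0.89 of siRpl14, without a 2C-like rise. No test here decides that hypothesis, and a direct effect of Rpl11 and off-target effects were not tested.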

How the results depend on the processing

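The removal of genes overlapping an opposite-strand gene and the camera forms with a trend and on ranks were chosen after the results were seen. No call of a gene or list turned to a call in the other direction in the tests that were rerun, but some list medians and balances of directions changed sign, as given below. Causes were not tested, except that a stricter filter or an omitted library leaves fewer genes or samples. In sets 1 and 3 a group left with 1 library was assumed to vary like the others.

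Counts of genes past the threshold are given in the order siRpl14, siRpl11, both against siNT, both against siRpl14 and interaction in set 1, then siRpl14, siDux, both against siNT, both against siRpl14 and interaction in set 3, which were 3822, 5377, 5043, 878, 544, 87, 1, 135, 2 and 2. Counts that moved by over 1.5 times are given by setting. The stricter filter gave 2385 for siRpl14, 345 for both against siRpl14 and 145 for the interaction in set 1, and 7 for both against siRpl14 in set 3. It left 7 members of the 2C-like list in set 3, with a median of 1.18 for siRpl14 that no longer passed (adjusted p = 0.325, against 1.16e-07 to 0.00212 in the other settings with the preset correlation). Its medians were described without a new test for the other lists: histones with siRpl11 added to siRpl14 in set 1 went from 0.184 to -0.315 (7 members) and early lineage markers for siRpl14+siDux against siNT from 1.059 to -0.047 (2 members). In set 3 ATF4 genes for siRpl14 went from -0.697 to -0.359, and the 2C-like list for siDux from -0.958 to -2.047 and for siRpl14+siDux against siNT from -0.589 to -1.371. Other called medians that moved by over 1.5 times were histones for siRpl14 (-0.168 to -0.622) and the interaction (0.335 to 0.595), trophectoderm with siRpl11 added (-0.383 to -1.019) and early lineage markers for siRpl11 (0.562 to 1.439) and both against siNT (0.578 to 1.448) in set 1, and in set 3 trophectoderm for siRpl14+siDux against siNT (0.83 to 1.408) and the 2C-like interaction (-0.838 to -0.414). All libraries of the table gave 5904, 1444 and 1811 for siRpl14, both against siRpl14 and the interaction in set 1, and 2 for siDux and 4 for the interaction in set 3. Median-ratio rescaling moved the ribosomal protein median for siRpl11 from 0.119 to 0.239 and for siRpl14 in set 3 from -0.135 to -0.079. With siRpl11 added to siRpl14 in set 1 it moved that median from 0.194 to 0.303. Quantile normalization gave 463 for both against siRpl14 in set 1, and moved the ribosomal protein median for siRpl14 from -0.177 to 0.014 and the 2C-like median for siRpl11 from -0.16 to 0.03, the trophectoderm median with siRpl11 added from -0.383 to -0.19 and the 2C-like median for siRpl14+siDux against siNT from -0.589 to -0.385. No filter gave 313 for the interaction in set 1, and 54 for siRpl14 and 1 for the interaction in set 3. A pseudocount of 0.1 gave 16 for both against siRpl14 in set 3. Without trend and robust moderation set 3 gave 36 for siRpl14, 3 for siDux, 19 for both against siRpl14 and 13 for the interaction. Without genes overlapping an opposite-strand gene set 3 gave 39, 0, 76, 0 and 0. The replicate block gave 539 and 27 for both against siRpl14 and the interaction in set 1, and 0 for siDux and 1 for each of both against siRpl14 and the interaction in set 3. Deviations of replicate 1 in set 1 correlated at 0.178 to 0.497 among siNT, siRpl11 and siRpl14 and at -0.495 to -0.244 between these and siRpl14+siRpl11, so a structure shared by replicates cannot be ruled out, and the fits without a block do not model it. In set 3 they correlated at 0.039 to 0.063. A block assumes the same sign in all groups, which does not hold in set 1. There the more depleted library was replicate 2 with siRpl14 (Rpl14 at 27.1% against 60.2% of siNT) and with siRpl11 (Rpl11 at 15.2% against 34.9%). With both siRNAs it was replicate 1 (Rpl14 at 15.6% against 35.3%, Rpl11 at 13.2% against 33.4%). Whether depletion underlies the correlations was not tested, and siNT, which had none, correlated with the other groups too.

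With 1 library left out at a time the counts ranged over 752 to 3851, 1778 to 5592, 1307 to 5255, 79 to 670 and 2 to 1199 in set 1 and over 8 to 45, 0 to 0, 26 to 90, 0 to 3 and 0 to 2 in set 3. The p53 median for siRpl14+siDux against siRpl14 in set 3 ranged from -0.087 (without siRpl14 replicate 2) to 0.144. Genes raised by siRpl14 in set 3 had medians of -0.488 to -0.283 with siRpl11 added in set 1, and -0.497 without trend and robust moderation, where the call was lost. Genes raised in set 1 had medians of -0.095 to 0.043 with siDux added in set 3, and 0 with no filter, with median-ratio rescaling and with quantile normalization. Of 121 calls of named genes 69 were lost without some library.

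Of 71 list calls in 170 tests, 4 held with an estimated correlation: 2C-like and p53 for siRpl14 in set 3, p53 for siRpl14+siDux against siNT and 2C-like for siRpl14+siDux against siRpl14. Calls lost included those with medians of 1.346 (2C-like) and 0.89 (p53) for siRpl14 in set 1 and of -1.451 and -0.609 for siRpl11 added to it. Against no change, which is another question than camera's, fry did not pass for 40 of the 71 calls, that of -0.609 among them, and passed for 5 that camera did not call (feeder markers in the 3 comparisons with siNT in set 1, trophectoderm and interferon response for siRpl14 in set 3). The trend form gained ribosome biogenesis and the replicate block trophectoderm, both for siRpl14 in set 3. The ranked form lost 4 (cholesterol synthesis in both combined knockdowns against siRpl14, interferon response for siRpl14+siDux against siNT, the 2C-like interaction in set 3) and gained 2 (pluripotency for siRpl11 and for the interaction in set 1). In the simulated data a 2-fold change was recovered for 1.49% of the genes so changed in set 3 and 70.1% in set 1. All of these had a mean of at least 5 FPKM. Lower depth and the larger spread between replicates were not told apart as reasons.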

Other observations

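The 3 tests of counting without regard to strand in set 3 were chosen after the result was seen; the other 3 tests of that pattern were written before.

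Some lists did not pass camera in the comparisons of siRpl14 with siNT. In set 1 the primitive endoderm list had a median of 0.21 (2 of 14 higher and 1 lower, camera adjusted p = 0.876), trophectoderm 0.20 (5 higher and 2 lower of 16, adjusted p = 0.387), fibroblast feeder markers -0.19 (Thy1 and Pdgfrb lower of 9, adjusted p = 0.33), interferon response -0.40 (2 higher and 4 lower of 13, adjusted p = 0.0871) and germline genes 0.23 (3 higher and 1 lower of 17, adjusted p = 0.829). In set 3 their medians were 0.36, 0.53, -0.32, -0.44 and 0.09, with camera adjusted p = 0.113, 0.08, 0.68, 0.113 and 0.208. Trophectoderm in set 3 passed camera with the replicate block (adjusted p = 0.046). Tested against no change rather than against other genes, fry passed for trophectoderm and interferon response in set 3 (adjusted p = 0.0453 for each) and feeder markers in set 1 (adjusted p = 0.0477). Histone genes did not pass there (median 0.41, 12 measured, adjusted p = 0.319), nor did ribosome biogenesis (median 0.08, adjusted p = 0.08).

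Trophectoderm markers moved in the set 2 libraries, without replicates. Their median was 1.16 with siRpl14 and 1.58 with siRpl14+siDux against siNT, and 0.37 between these, above all 10000 random lists (central 95% from -0.07 to 0.15). Cdkn1a was at 125 FPKM with siRpl14 and 156 with siRpl14+siDux against 45.3, and Nanog at 221 and 189 against 449.

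The set 3 table gives signal to other genes than the table of sets 1 and 2. There were 107 genes under 1 FPKM in all 12 libraries of sets 1 and 2 and at 20 or more in all 10 of set 3, such as Acat3 (means of 0.0776 and 2717 FPKM), whose exons overlap Tcp1 on the opposite strand, so lower depth alone was argued against. Reads from genomic DNA spread over all genes were argued against as a source of such levels, since 9640 low genes with no opposite-strand gene had a median of 0. The 10th percentile of values above 0 was 1.08 to 1.6 FPKM in set 3, so sparse genomic reads below that cannot be excluded. Crediting unspliced fragments to the wrong strand was argued against by the limit written before, a relative log2 loss of 1 for single-exon genes. Among expressed genes with no opposite-strand gene, these changed by -1.55 and genes of several exons by -1.34, a difference of -0.212. With 2 to 3, 4 to 8 and 9 or more exons the change was -1.57, -1.46 and -1.25. A smaller effect that depends on exon number therefore stays open. Of the 107 genes 98 had a known structure. Of these 92.9% overlap a gene on the opposite strand, against 9.92% of other low genes. For a partner at 10 FPKM or more the shares were 54.1% and 2.32%. Those are the places that counting without regard to strand would raise. If such counting set their level, about the level of the partner or less was predicted. The median ratio to the higher mean of the partner was 8.16, and all 91 genes lay above it. Cd247 was at 1356 FPKM beside Pou2f1 at 16.0. This cannot decide the question, since FPKM is scaled by transcript length, so a shorter gene can exceed its partner. The genes were also chosen for being high in set 3. Counting without regard to strand was argued against as the cause of loss for 3 genes, which have no opposite-strand gene. These (Tmem256, Dpm3 and Snord22) were at 20 FPKM or more in sets 1 and 2 and at 0 in all of set 3. The pattern stays open, and no biological explanation was tested.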
